A study of Homo sapiens with 12 samples.

How the data were processed

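Poly-A RNA of RD cells was captured on poly-T beads and made into libraries with an NEBNext Ultra kit, per the labels' protocols. The cells had received scrambled or EHMT1 siRNA with Lipofectamine RNAiMAX 48 h before collection. The submitters' processing notes name CASAVA, bcl2fastq, STAR 2.5, HTSeq 0.6.1, DESeq2 and the genome build hg19. The deposited values were raw counts per gene that the authors made, with no normalization, 1 file per library in the layout of the STAR aligner's gene count table: an unstranded column and a column for each strand. This layout is that of STAR and not of HTSeq. Each file listed 61552 gene identifiers, of which 58352 were in GENCODE release 29 on GRCh38 and 61399 in the table of gene names. This set of identifiers is later than the hg19 build named in the notes, so no coordinates are given.

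Reads that named no gene stayed out of library sizes and tests. They were 20.0% to 21.2% of all reads: 4.90% to 5.84% in no feature, 9.94% to 10.3% ambiguous, 1.96% to 2.15% multimapping and 2.54% to 3.28% unmapped. The second strand column held 87.1% to 89.0% of the strand counts although the kit named is not described as directional. The unstranded column was used for the main results and each strand column as an alternative. In the unstranded column, reads from genes that overlap, or from an antisense partner, cannot be told apart, so the values of such genes are uncertain, as are those of genes with near-identical copies.

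Gene counts ranged from 40639655 to 47258481 per library, and 26714 to 29265 genes had a count. A gene with 0 counts could still lie at up to 0.0635 to 0.0738 CPM, the level of 3 counts; such floors cover counting error only. Pairs of libraries of 1 group differed by more than sampling noise, with a chi-square per degree of freedom of 9.04 to 21.4 among scrambled and 2.99 to 3.39 among EHMT1 siRNA libraries, so each counted as 1 sample. The labels do not say that the replicates were separate cultures, so p-values measure the spread between these samples, which may be technical. The fit described below takes the same spread for both groups, so its p-values average over groups of unequal spread.

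Groups came from the sample titles. Counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr (minimum count 10), TMM normalization, a robust quasi-likelihood fit on group alone, the quasi-likelihood F test and Benjamini-Hochberg adjustment, with a threshold of 0.05. SEs were the absolute log2 fold change divided by the square root of the F statistic. CPM values are counts scaled to library size with TMM factors. The square root of the common dispersion was 0.0663. EHMT1, EHMT2 and SOX8 also had an exact two-sided permutation test on log2 CPM.

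The test, the groups, the 26 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule named EHMT1, EHMT2 and SOX8. It also named the 10 largest rises and 10 largest falls among called protein-coding genes with an average log2 CPM of at least 1 and no overlap between the groups' libraries. From each list it named up to 4 tested members with the smallest adjusted p. Genes named outside the rule are marked as such, and 1 list and some genes that the rule names are not reported here. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the 26 lists, and with an estimated correlation and fry beside it. With an estimated correlation no list was called: adjusted p was 0.0767 for matrix proteases and 0.148 for cell cycle genes, the lowest of the 26. That form of the test also takes its degrees of freedom from the few libraries, which raises p by itself. For matrix proteases the estimated correlation was -0.018, below the preset 0.01, so genes varying together did not cause the loss of that call. For cell cycle genes it was 0.142, and both may count. A call lost in this form thus does not show that a list's genes vary together. Fry, which asks whether a list's genes move one way on balance and does not compare them with other genes, called the cell cycle list (adjusted p = 0.00785), the matrix protease list (0.00286) and the p53 list (0.0345).

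On simulated data with 18646 genes drawn from the means and depths of the EHMT1 siRNA comparison, edgeR recovered 46% of genes changed by 1.25-fold, 62% by 1.5-fold, 78% by 2-fold and 98% by 3-fold, and 4.05% of its calls were false. With no gene changed it called 2 genes, and camera called 0 lists. Simulated genes were drawn independently, with equal spread in both groups, and far fewer were changed than were called in the real data. The rates may therefore differ in the real data, and the simulation does not test lists whose genes vary together.

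Alternatives were other size factors (RLE, upper quartile), no filter or a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a replicate block, each strand column, an adjusted p threshold of 0.01 for counts of genes, and leaving out each library. A correction for GC content and gene length, over the 97.5% of tested genes with both values, was added after the data were seen. Words of 7 bases were counted in the longest annotated 3′ UTR (at least 100 bases) of 13247 protein-coding genes from GENCODE release 29, with words in at least 50 genes scored against 1000 random gene sets matched on UTR length (20 bins) and GC content (5 bins). This used Python 3.11.15 and numpy 2.4.6.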

Results

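Poly-A RNA was sequenced from RD cells, an established human cell line from an embryonal rhabdomyosarcoma, a soft tissue tumour whose cells resemble immature skeletal muscle. The cells had been transfected with small interfering RNA (siRNA), short double-stranded RNA that guides the breakdown of a matching transcript. A non-targeting scrambled siRNA (n = 3 libraries) was compared with an siRNA against EHMT1 (n = 3 libraries), with RNA taken 48 h after transfection. EHMT1, also called GLP, is a histone methyltransferase that places methyl groups on lysine 9 of histone H3 together with its partner EHMT2 (G9a). The libraries held 47258481, 41095515 and 41895647 gene counts in scrambled replicates 1, 2 and 3, and 42098426, 41176051 and 40639655 in EHMT1 siRNA replicates 1, 2 and 3. The other 6 libraries of the series, from a SOX8 siRNA experiment, were not analysed here.

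The first question was whether the targeted transcript was lower in the libraries labelled as EHMT1 siRNA. EHMT1 (ENSG00000181090) fell from 139 ± 14.7 CPM (SD, n = 3) with scrambled siRNA to 55.1 ± 2.26 CPM (SD, n = 3), leaving 39.6% of its level. The log2 fold change was -1.34 (SE 0.072, edgeR adjusted p = 9.13e-09), and each EHMT1 siRNA library lay below each scrambled library. EHMT2 (ENSG00000204371) fell from 106.1 ± 7.77 to 91.7 ± 1.64 CPM (SD, n = 3 each), a log2 change of -0.21 (SE 0.061, edgeR adjusted p = 0.0334), a call that was lost when any 1 of the 3 EHMT1 siRNA libraries was left out. An exact two-sided permutation test gave p = 0.1 for each of these genes, the smallest value that 3 against 3 libraries allow.

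The series title names SOX8, a transcription factor of the SOXE group, as a gene whose expression depends on EHMT1, so its level was the next comparison. SOX8 (ENSG00000005513) fell from 220.7 ± 18.4 CPM with scrambled siRNA to 162.8 ± 6.45 CPM with EHMT1 siRNA (SD, n = 3 each), which left 73.8% of its level. The log2 fold change was -0.44 (SE 0.065, edgeR adjusted p = 0.000305), and the groups of libraries did not overlap. The SOX8 3′ UTR held 4 of the 7 words of 7 bases that were enriched in the 3′ UTRs of fallen genes, SOX8 among them. The exact two-sided permutation test gave p = 0.1 for SOX8, again the smallest possible. Of the 10 SOX family genes tested, 2 fell and 0 rose: besides SOX8, SOX13 had a log2 change of -0.51 (edgeR adjusted p = 0.00171). SOX4 at -0.16 and SOX7 at 0.27 did not pass the test (edgeR adjusted p = 0.0958 and 0.151). Adjusted over the list alone, the count was also 2 fallen and 0 risen, and the set test against all other genes gave an adjusted p of 0.178. Leaving out 1 library gave 0 to 2 risen and 2 to 3 fallen SOX family genes.

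**Figure D1:**
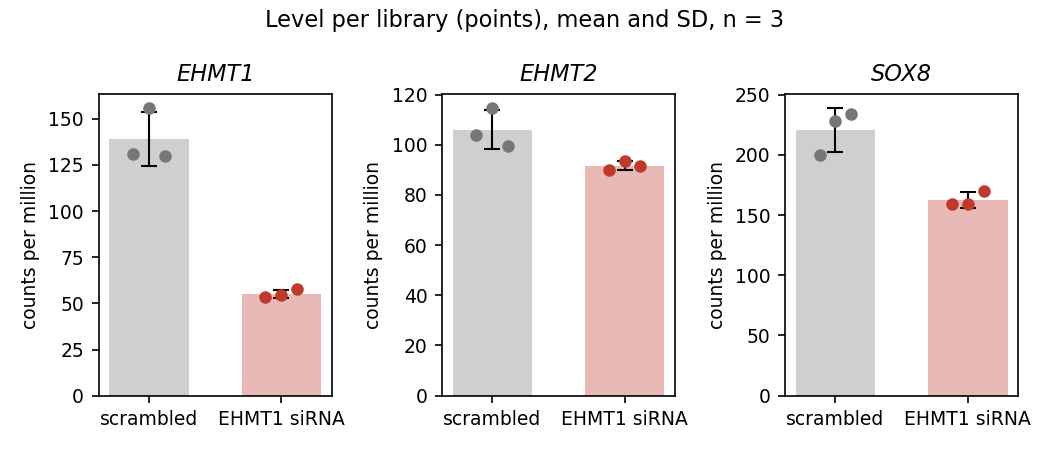
CPM (counts scaled to library size, y axes, starting at 0) of EHMT1, EHMT2 and SOX8 in the 3 scrambled and 3 EHMT1 siRNA libraries. Points are libraries, bars are group means and error bars are SDs (n = 3 each); EHMT1 drops from a mean of 139 to 55.1 and SOX8 from 220.7 to 162.8.

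The third question was which other transcripts differed between the groups. Of 18646 genes tested, 1084 rose and 1220 fell with EHMT1 siRNA, 12.4% of those tested (2304 genes, edgeR adjusted p under 0.05; 4774 at an unadjusted p under 0.05). Most changes were small: the median absolute log2 change of the called genes was 0.33, and 81.5% of them changed by less than 1.5-fold. At least 2-fold changes were found for 129 genes that rose and 33 that fell. Among the 13711 protein-coding genes tested, 959 rose and 1164 fell. The libraries of the groups did not overlap for 5760 genes, 30.9% of those tested, where chance gives 10% for 3 against 3.

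Under the rule for named genes, the largest rises were in genes at low levels. KRTAP2-3, a keratin-associated protein gene with close copies between which reads can be split, rose from 1.49 ± 0.191 to 4.29 ± 0.530 CPM (SD, n = 3 each), a log2 change of 1.52 (SE 0.168, edgeR adjusted p = 2.07e-05). SIGLEC15, a sialic acid-binding receptor, had a log2 change of 1.45, and IL31RA, a subunit of the interleukin-31 receptor, of 1.26. TIE1, a receptor tyrosine kinase of endothelium, rose by 1.18 and CD34, a surface glycoprotein of blood progenitors and endothelium, by 1.12. DOCK3, an exchange factor for the GTPase RAC1, rose by 1.11 and BANK1, a B-cell signalling scaffold, by 1.10. NKX3-2, a homeobox transcription factor, INHBE, an inhibin subunit, and MYH15, a myosin heavy chain, rose by 1.09, 1.07 and 1.06. Adjusted p in these 10 genes ran from 2.93e-06 for MYH15 to 0.0017 for INHBE (edgeR).

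The largest falls included genes at higher levels. GIPC1, a PDZ-domain adaptor of membrane trafficking, fell from 101.2 ± 9.79 to 39.0 ± 3.27 CPM (SD, n = 3 each), with a log2 change of -1.38 (SE 0.077, edgeR adjusted p = 1.17e-08). PACSIN2, a membrane-bending protein of endocytosis, fell from 97.6 to 42.5 mean CPM with a log2 change of -1.20 (edgeR adjusted p = 9.13e-09). TXNDC5, a protein disulfide isomerase, had the lowest log2 change at -1.40, close to EHMT1 itself. IGFBP3, which binds insulin-like growth factors, changed by -1.29 and NRARP, a Notch target that limits Notch signalling, by -1.21. The zinc finger gene ZIK1 changed by -1.17, EPB41L4B, a FERM-domain protein, by -1.11, TBX2, a T-box repressor, by -1.03 and MXRA5, a matrix protein, by -1.03. Adjusted p in these falls was at most 0.000122 (edgeR). Of the 10 largest falls, EHMT1 included, 9 held at least 1 of the enriched words in their 3′ UTR, TBX2 being the exception, against 2.4 expected from UTRs of similar content; the words had been picked on the fallen genes, these included.

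**Figure D2:**
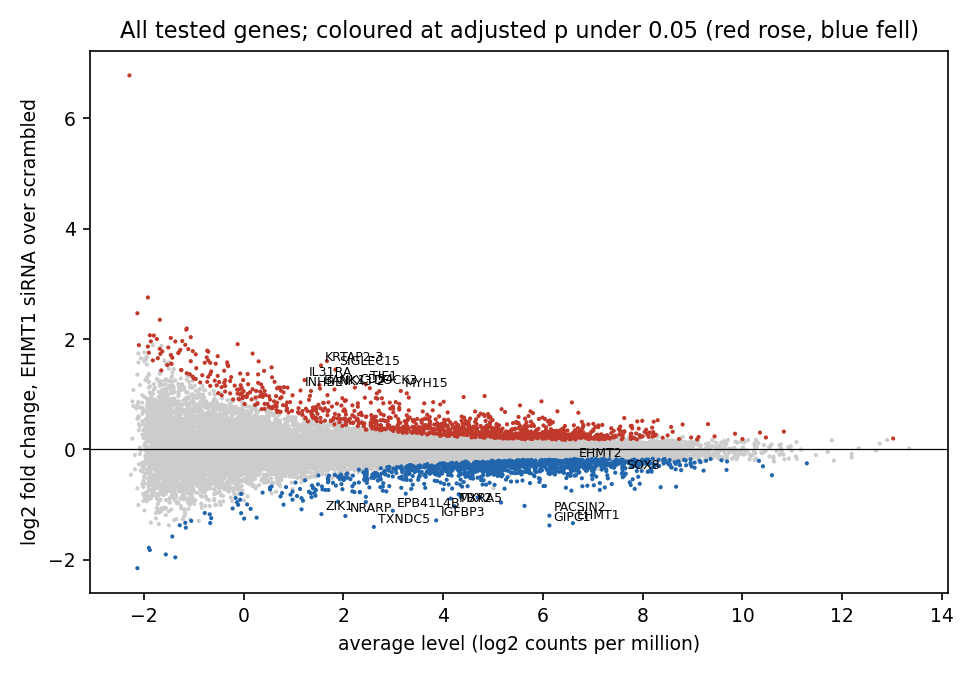
Log2 fold change of EHMT1 siRNA over scrambled siRNA (y axis) against average level in log2 CPM (x axis) for the 18646 genes tested, with genes that rose in red, genes that fell in blue and other genes in grey. The labelled rises lie at low average levels, whereas EHMT1, GIPC1 and PACSIN2 combine high levels with falls of at least 2-fold.

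**Figure D3:**
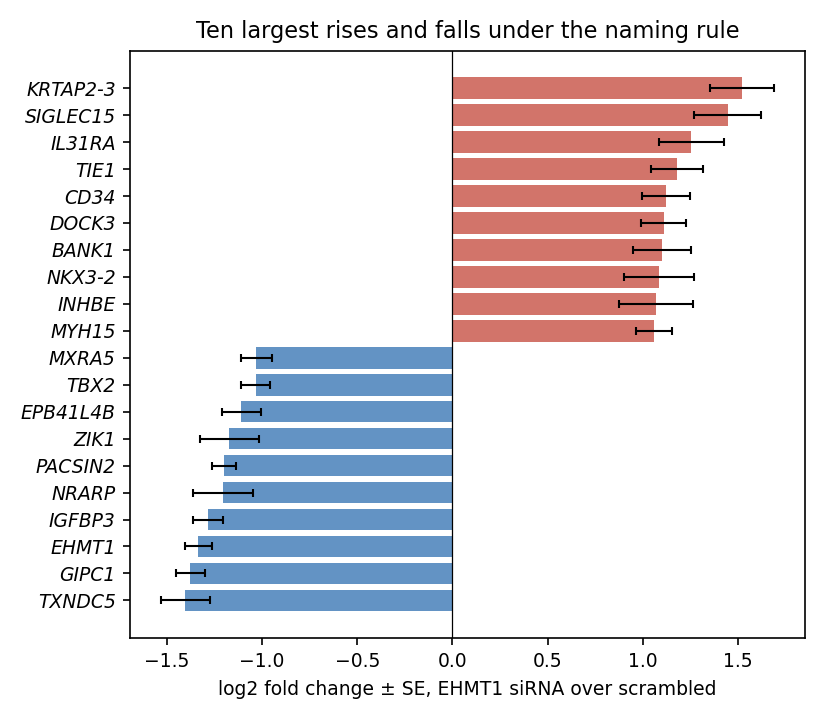
Log2 fold change (x axis) of the 10 largest rises and 10 largest falls under the rule for named genes, with bars for the estimate and error bars for its SE (3 libraries per group). KRTAP2-3 has the largest rise at 1.52 and TXNDC5 the largest fall at -1.40.

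Scrambled replicate 2 stood apart from the other libraries on the first principal component. It lay at -36.4 on the first principal component, which held 35.8% of the variance, against -16.0 and -9.20 for scrambled replicates 1 and 3 and 19.6 to 21.6 for the EHMT1 siRNA libraries. On the second component, which held 23.9% of the variance, scrambled replicate 1 lay furthest out, at 31.3, against -26.6 for scrambled replicate 2. The mitochondrial share of counts in scrambled replicate 2 was 5.41%, against 4.29% to 4.83% in the other 5. Without it, 1625 genes rose and 1923 fell. Leaving out EHMT1 siRNA replicate 1, 2 or 3 lowered the number of changed genes from 2304 to 1172, 936 or 1010.

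Most genes of the cell cycle list fell. Of 41 tested, 30 fell and 1 rose, and 31 fell and 2 rose when adjusted over the list alone; the median log2 change was -0.30. E2F1, a transcription factor that drives entry into S phase, changed by -0.47, the phosphatase gene CDC25A by -0.45, MCM2 of the replicative helicase by -0.49 and CENPF of the kinetochore by -0.39. CCND1, the cyclin of early G1, was the gene that rose, by 0.31 (named after its value was seen). The set test (camera, preset correlation) gave an adjusted p of 1.25e-20, and an adjusted p of 0.148 with an estimated correlation. With 1 library left out, 20 to 31 of the list fell, the fewest without EHMT1 siRNA replicate 2 and the most without scrambled replicate 2, and 3 fell in strand column 3. The 3′ UTRs of E2F1, CDC25A, MCM2 and CENPF held 0, 1, 2 and 0 of the enriched words.

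In the list of matrix proteases and inhibitors, 11 of 27 tested genes rose and 1 fell, or 13 and 1 adjusted over the list alone, with a median log2 change of 0.26. ADAM19, a membrane metalloprotease, rose by 0.69, the urokinase gene PLAU by 0.46, its receptor PLAUR by 0.45 and the lysosomal protease CTSB by 0.32. PLAU was abundant, at 533.6 ± 31.6 CPM with scrambled siRNA and 733.7 ± 6.64 CPM with EHMT1 siRNA (SD, n = 3 each). The gene that fell was TIMP3, a metalloprotease inhibitor, at -0.22 (named after its value was seen); this call was lost without scrambled replicate 3 or any 1 of the EHMT1 siRNA libraries. The set test gave an adjusted p of 1.12e-07, and an adjusted p of 0.0767 with an estimated correlation. With 1 library left out, 6 to 11 rose, and 3 in strand column 3.

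Notch and Hedgehog pathway genes fell more often than they rose. Of 29 tested, 8 fell and 1 rose, or 9 and 1 adjusted over the list alone, and the median log2 change was -0.13. The receptor NOTCH3 fell from 404.9 ± 24.4 to 251.9 ± 10.4 CPM (SD, n = 3 each), a log2 change of -0.69 (edgeR adjusted p = 2.27e-06). NRARP at -1.21 and HES4 at -0.71 are Notch targets, and CDON at -0.39 is a co-receptor for Hedgehog ligands. The 3′ UTRs of NOTCH3, NRARP and CDON held 0, 1 and 5 of the enriched words, and none was searched for HES4. MFNG, which modifies Notch receptors, rose by 1.41 with an edgeR adjusted p of 0.0378 (named after its value was seen), a call lost without scrambled replicate 3 or any 1 of the EHMT1 siRNA libraries. It lay near the floor, at a mean of 0.321 and 0.866 CPM, was removed by a filter of at least 1 CPM in 3 libraries and had no adjusted p in DESeq2. The set test gave an adjusted p of 0.000895, and an adjusted p of 0.624 with an estimated correlation. With 1 library left out, 6 to 10 fell, and 3 in strand column 3.

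Among muscle differentiation genes, 8 of 36 tested rose and 1 fell, or 11 and 3 adjusted over the list alone, with a median log2 change of 0.10. CHRNG and CHRND, subunits of the muscle acetylcholine receptor, rose by 0.83 and 0.41, and the myosin light chain genes MYL1 and MYL4 by 0.59 and 0.90. ACTN3, an actinin of fast fibres, fell, with a log2 change of -0.70 (named after its value was seen; the call was lost without EHMT1 siRNA replicate 2). The set test gave an adjusted p of 0.0193, and an adjusted p of 0.727 with an estimated correlation. The call of the list was also lost without scrambled replicate 1 (adjusted p = 0.305). With 1 library left out, 6 to 11 rose and 0 to 5 fell, and 0 rose in strand column 3. Of 19 myogenic regulators tested, 1 rose and 0 fell, the same count as when adjusted over the list alone (set test adjusted p = 0.635). PAX7, a factor of muscle stem cells, rose by 0.28, a call lost without EHMT1 siRNA replicate 3, while SMYD1 at 0.34 and EYA2 at -0.69 did not pass the test.

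**Figure D4:**
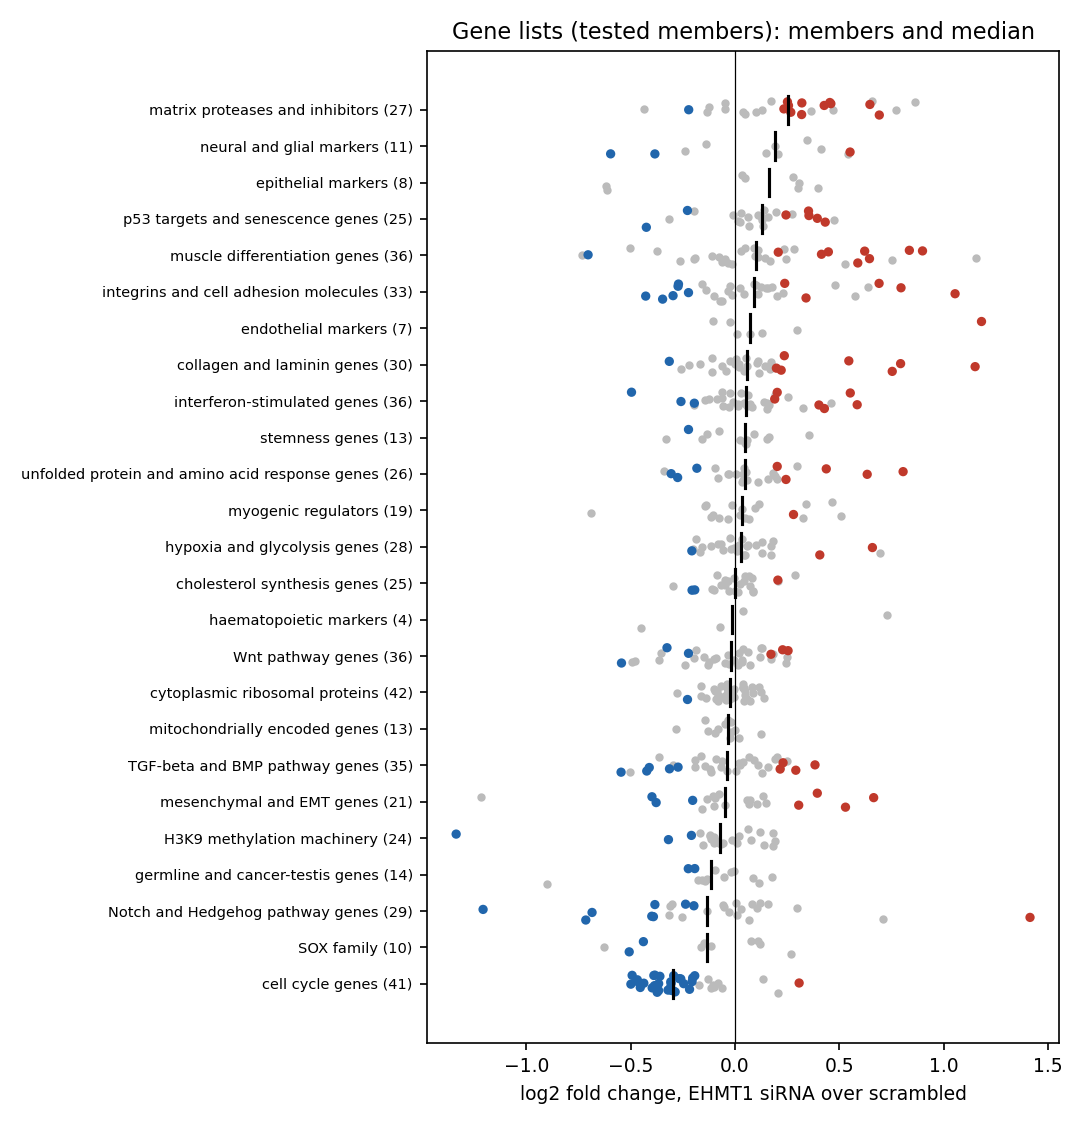
Log2 fold change of EHMT1 siRNA over scrambled siRNA (x axis) for each tested member of the gene lists reported here (y axis, number tested in parentheses), with genes that rose in red, genes that fell in blue, others in grey and the list median as a black line. Cell cycle genes have the lowest median, -0.30, and matrix proteases and inhibitors the highest, 0.26.

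The lists on mesenchymal state, adhesion and matrix moved both ways. Mesenchymal and EMT (epithelial-mesenchymal transition) genes had 4 of 21 that rose and 3 that fell, also 4 and 3 adjusted over the list alone. LOX, a collagen cross-linking enzyme, rose by 0.66 and TGFBI by 0.39, and THY1 changed by -0.40; the list's median was -0.05 and its mean -0.02, while the set test pointed up (adjusted p = 0.556). Integrins and cell adhesion molecules had 5 of 33 that rose and 6 that fell (10 and 6 adjusted over the list alone; set test adjusted p = 0.175). ITGA3 at 0.69, ITGA11 at 1.05 and ITGA10 at 0.80 rose, and SDC1, a heparan sulfate proteoglycan, changed by -0.43. Collagen and laminin genes had 7 of 30 that rose and 1 that fell (9 and 4 adjusted over the list alone; set test adjusted p = 0.0536), with LAMB3 at 0.75, COL1A2 at 0.55, LAMA2 at 0.22 and COL15A1 at -0.32. The call of LAMA2 was lost without any 1 of the EHMT1 siRNA libraries and that of COL15A1 without replicate 1 or 2. Risen collagen and laminin genes numbered 2 to 13 and fallen ones 0 to 3 with 1 library left out.

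In the list of H3K9 methylation machinery, 3 of 24 tested genes fell and 0 rose; adjusted over the list alone, 3 fell and 1 rose. The 3 were EHMT1, EHMT2 and CBX1, a heterochromatin protein, at -0.32, while the demethylase gene KDM4B was at 0.19 and did not pass the test (edgeR adjusted p = 0.0527). The set test gave an adjusted p of 0.0505, a value to which EHMT1, the target of the siRNA, contributes. Leaving out 1 library gave 0 to 2 risen and 2 to 4 fallen members.

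Signalling and stress lists held changes in both directions, and camera called none of them. TGF-beta and BMP pathway genes had 4 of 35 that rose and 5 that fell (5 and 7 adjusted over the list alone, set test adjusted p = 0.749). Leaving out 1 library gave 1 to 5 risen and 3 to 5 fallen. ID1 and ID3, BMP targets that block differentiation factors, changed by -0.55 and -0.42, and CCN2 and the BMP antagonist NOG rose by 0.38 and 0.29; the call of NOG was lost without EHMT1 siRNA replicate 3, and that of ID1 with GC content and length corrected. Wnt pathway genes had 3 of 36 that rose and 3 that fell (3 and 3 adjusted over the list alone; set test adjusted p = 0.612), with FZD5 at -0.54, DKK1 at -0.33, MYC at -0.22 and DKK3 at 0.25. The calls of MYC, DKK1 and DKK3 depended on single EHMT1 siRNA libraries: MYC was lost without any 1 of the 3, DKK1 without replicate 2 or 3 or scrambled replicate 1, and DKK3 without replicate 3. Of 25 p53 targets and senescence genes, 5 rose and 2 fell (7 and 3 adjusted over the list alone). The set test adjusted p was 0.0923, and the adjusted p 0.0345 by fry, which does not compare the list with other genes. Leaving out 1 library gave 2 to 6 risen and 1 to 3 fallen. CDKN2B, SERTAD1 and TP53I3 rose by 0.35, 0.35 and 0.24, and PMAIP1, an inducer of apoptosis, changed by -0.42; the call of TP53I3 was lost without any 1 of the EHMT1 siRNA libraries. Of 36 interferon-stimulated genes, 6 rose and 3 fell (9 and 3 adjusted over the list alone, set test adjusted p = 0.191). IFIT3 was at -0.50, IFITM1 at 0.58, TAP1 at 0.43 and IRF7 at 0.40, the last lost without EHMT1 siRNA replicate 2. Risen interferon-stimulated genes numbered 2 to 9 and fallen ones 1 to 3 with 1 library left out.

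Of 26 unfolded protein and amino acid response genes, 5 rose and 3 fell (7 and 3 adjusted over the list alone, set test adjusted p = 0.191). Leaving out 1 library gave 1 to 6 risen and 1 to 4 fallen. The chaperone genes HSPA5 and HYOU1 changed by -0.31 and -0.28, and DNAJB9 and CHAC1 rose by 0.44 and 0.63. The call of HYOU1 was lost without any 1 of the EHMT1 siRNA libraries and that of CHAC1 without replicate 2 or 3. Of 28 hypoxia and glycolysis genes, 2 rose and 1 fell (5 and 2 adjusted over the list alone; set test adjusted p = 0.276). NDRG1 and the glucose transporter SLC2A3 rose by 0.66 and 0.41, ENO1 changed by -0.21, a call lost without any 1 of the EHMT1 siRNA libraries, and SLC2A1 at 0.17 did not pass the test. Of 25 cholesterol synthesis genes, 1 rose and 2 fell, also when adjusted over the list alone (set test adjusted p = 0.877). SC5D was at 0.20 and IDI1 at -0.21, and EBP at -0.30 did not pass the test; the calls of SC5D and IDI1 were lost without scrambled replicate 3 or any 1 of the EHMT1 siRNA libraries, and that of IDI1 also without scrambled replicate 1. Of 42 cytoplasmic ribosomal protein genes, 1 fell and 0 rose, and 0 changed when adjusted over the list alone (set test adjusted p = 0.556). RPS27 was at -0.23, a call lost without EHMT1 siRNA replicate 1 or 2, and RPL30 at -0.28, RPLP0 at -0.16 and RPL11 at -0.16 did not pass; these genes can share reads with pseudogenes.

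Of 13 stemness genes, 1 fell and 0 rose, also when adjusted over the list alone, and this was MYC, whose call was lost without any 1 of the EHMT1 siRNA libraries; ALDH1A2 at -0.33, KLF4 at -0.16 and IGF2 at 0.16 did not pass. The list's median was 0.05 and its mean 0.00, while the set test pointed down (adjusted p = 0.758). Of 14 germline and cancer-testis genes, 2 fell and 0 rose, or 3 and 0 adjusted over the list alone (set test adjusted p = 0.121). MAGEA3 and MAGEA12 were at -0.22 and -0.19, both members of a family of near-identical genes, and MAGEA10 at -0.18 and XAGE1A at -0.90 did not pass. Both calls were lost without scrambled replicate 1 or any 1 of the EHMT1 siRNA libraries, and that of MAGEA12 also without scrambled replicate 3, with upper-quartile factors and with no filter on low counts.

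Markers of other cell types were compared between the groups. A fold change cannot show whether other cells were present in both groups alike. Many markers had too few counts to be tested. The filter kept 8 of 18 epithelial, 4 of 18 haematopoietic, 7 of 12 endothelial and 11 of 20 neural and glial markers. Of 8 epithelial and 4 haematopoietic markers tested, 0 changed by edgeR over all genes or adjusted over the list alone, and 0 by DESeq2; 4 epithelial and 0 haematopoietic markers had an unadjusted p under 0.05 (edgeR). The values nearest to the threshold were 0.30 for KRT8, 0.31 for CLDN4, -0.62 for PROM2 and 0.28 for OCLN among epithelial markers (set test adjusted p = 0.556). Among haematopoietic markers they were 0.73 for CSF1R, -0.45 for CD14, -0.07 for CD4 and 0.04 for CORO1A (set test adjusted p = 0.89). Of 7 endothelial markers, 1 rose and 0 fell, also when adjusted over the list alone: TIE1 rose, and FLT1 at 0.13, CLDN5 at 0.29 and EGFL7 at -0.10 did not pass (set test adjusted p = 0.175). Of 11 neural and glial markers, 1 rose and 2 fell, or 2 and 2 adjusted over the list alone. The neurofilament genes NEFM and NEFL were at -0.60 and -0.38, and SYP at 0.34 did not pass; the median was 0.19 and the mean 0.09, while the set test pointed down (adjusted p = 0.758). Of 13 mitochondrially encoded genes, 0 changed by edgeR over all genes or adjusted over the list alone, 0 by DESeq2, and 1 had an unadjusted p under 0.05 (set test adjusted p = 0.612), with MT-ATP8 at -0.28, MT-CO3 at -0.14, MT-ND3 at 0.12 and MT-ATP6 at -0.13. Leaving out 1 library gave 0 to 4 risen and 0 to 1 fallen mitochondrially encoded genes by edgeR.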

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

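The correction for GC content and length was chosen after the data were seen; the other alternatives were planned. EHMT1 and SOX8 kept their direction and their call under every alternative, with log2 changes of -1.38 to -1.25 for EHMT1 and -0.51 to -0.40 for SOX8 when 1 library was left out. The main counts were 2304 changed genes (1084 rose, 1220 fell) and 162 changed at least 2-fold (129 rose, 33 fell). Strand column 3, which holds few reads, gave 177 (90 rose, 87 fell) and 32 (18 and 14). An adjusted p under 0.01 gave 1017 (492 and 525) and 72 (58 and 14). GC and length correction gave 3480 genes, with 1857 fallen. At least 2-fold changes numbered 67 (54 and 13) with at least 1 CPM in 3 libraries, where fewer genes are tested, and 78 (60 and 18) with DESeq2, for which the cause was not tested. Leaving out 1 library gave 936 to 3548 changed genes, 452 to 1625 risen and 484 to 1923 fallen, and at least 2-fold 75 to 187, 61 to 149 and 14 to 38. Without a scrambled library the counts were 2190, 3548 and 2220, and without an EHMT1 siRNA library 1172, 936 and 1010. The fit takes the same spread for both groups, although scrambled libraries differed more among themselves than EHMT1 siRNA libraries. Leaving out a library of the tighter group gives the wider group more weight in that spread. Whether this caused the difference in counts was not tested. Of the 2304 genes, 2102 were also called in the same direction by DESeq2, 2109 with strand column 4 and 2185 without scrambled replicate 2.

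The labels link the samples only by a replicate number. Deviations of same-numbered libraries correlated at 0.056, 0.015 and 0.025. Each library correlated best with its own number except scrambled replicate 2 (0.019 with number 3). Unmapped reads, scrambled then EHMT1 siRNA, were 2.536% and 2.543% for number 1, 3.111% and 3.121% for number 2, and 3.275% and 2.965% for number 3. Whether the numbers mark a shared batch was not tested. The replicate block raised the count to 3106, with 2303 of the 2304 genes shared.

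With an estimated correlation, adjusted p was 0.0767 for matrix proteases, 0.727 for muscle differentiation, 0.148 for cell cycle and 0.624 for Notch and Hedgehog genes; fry gave 0.234 for the muscle and 0.0975 for the Notch list. Leaving out 1 library gave 0.000605 to 0.305 for the muscle list. Counts of risen or fallen list members were weaker in 118 and stronger in 78 comparisons with an alternative.

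Over all 2304 genes, 146 had the opposite sign in strand column 3 and 2 in strand column 4. Among named genes, signs turned only where the main result was not called, except for FZD5, which was 0.293 in strand column 3, the column with fewer reads. There EBP was 0.17, RPL30 0.068 and MT-ND3 -0.17; in strand column 4 RPL30 was 0.10 and CORO1A -0.016. Leaving out 1 library gave -0.239 to 0.033 for MT-ATP6, -0.24 to 0.16 for CD4 and -0.094 to 0.118 for CORO1A. The direction of the set test turned without 1 library for myogenic regulators (adjusted p 0.369 to 0.773 over the libraries), TGF-beta and BMP (0.409 to 0.951), cholesterol (0.379 to 0.951), mitochondrially encoded (0.0502 to 0.751) and haematopoietic genes (0.785 to 0.994; 0.731 in strand column 4). The causes were not tested. Of the 88 named genes that passed the main test, 71 passed without EHMT1 siRNA replicate 2 or 3 and 18 in strand column 3. Simulated at this depth and number of libraries, with equal spread in both groups, changes of 1.25-fold were recovered in 46% of genes. Depth was not varied.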

Other observations

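Tests set down before their results were the highest word scores, the reverse complements, the presence of words in EHMT1 and SOX8, the share of fallen cell cycle genes with a word, the counts of cell cycle genes without scrambled replicate 2 and with GC content and length corrected, the ratio of 2-fold rises to falls without that library, the pooled strand share and the edgeR count in other splits. All else in this part was chosen after results were seen, which includes the families of gene symbols, the shares with a word among all falls and the larger ones, and the genes named with families, ITGB1, RPL24, RPL24P4 and RN7SL1. Among 186 families with at least 10 tested members, genes with ZNF symbols, mostly zinc finger transcription factors, fell more often than they rose: of 518 tested, 106 fell, 5 rose and the others did not pass the test, with a median log2 change of -0.11 (camera adjusted p = 1.16e-06, and adjusted p = 0.919 with an estimated correlation). With an estimated correlation, the families named here and many that were not called shared the camera adjusted p of 0.919. That value therefore does not tell them apart. ZNF740, ZNF787, ZNF395 and ZNF667 changed by -0.61, -0.66, -0.64 and -0.71. The median stayed below 0 with RLE factors (-0.11), with upper-quartile factors (-0.09) and without scrambled replicate 2 (-0.13; 142 fell and 11 rose). Of 57 genes with EIF symbols, which include the translation initiation factors, 11 fell and 0 rose (camera adjusted p = 0.00162, and 0.919 with an estimated correlation); 7 fell with upper-quartile factors and 14 without scrambled replicate 2. EIF4EBP2, a repressor of cap-dependent translation, was at -0.48 and EIF2S3, a subunit of initiation factor eIF2, at -0.33.

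Of 12 integrin alpha chain genes tested, 5 rose and 0 fell: ITGA3, ITGA11, ITGA10, ITGA1 at 0.34 and ITGA6 at 0.24, the last lost without EHMT1 siRNA replicate 1 or 2 (camera adjusted p = 1.12e-05, and 0.919 with an estimated correlation). The beta chain ITGB1, which pairs with each of these 5, was at -0.27 (edgeR adjusted p = 0.00719; the call was lost without EHMT1 siRNA replicate 3). Long non-coding RNA genes with LINC symbols went up more often than down, 25 against 5 of 328 (camera adjusted p = 0.0374, and 0.919 with an estimated correlation). They lie at low levels. Among tested protein-coding genes, which do not include them, the tenth with the lowest average level had a median log2 change of 0.11. RPL24 changed by -0.68 and its pseudogene RPL24P4, with which it can share reads, by -1.08. RN7SL1, the RNA of the signal recognition particle, rose by 0.87. How well poly-A capture measures this RNA was not tested.

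Some short words were more frequent in the 3′ UTRs of genes that fell, a pattern that an siRNA can leave when the seed of its guide strand pairs with other transcripts: among 1134 fallen genes the highest word score was 6.17, for CGAGTCT, against a 95th percentile of 4.85 in random gene sets (permutation p = 0.001, the smallest that 1000 permutations can give), and all 7 words above it held GAGTC. Most fallen genes held none of these words: 403 held at least 1 against 269.8 in UTRs of similar content, with 44.8% against 22.6% among falls of at least 1.5-fold and 9 of the 10 largest falls (2.4 expected), and since the words were picked on these genes the excess only describes how many falls they could account for. The words' reverse complements scored at most 1.11, which argues against a motif of double-stranded DNA. Among risen genes 1 word, TTTGCAC, passed with 5.06 against 4.92 (permutation p = 0.032). Seed matches of the scrambled siRNA could leave such a word, but the test cannot tell them from other sources of it. Of the words, 4 were in the longest EHMT1 transcript, 6 over all EHMT1 protein-coding transcripts, and 4, in part overlapping, in the SOX8 3′ UTR. However, 60.7% of transcripts as long as EHMT1 and 22.2% of UTRs like that of SOX8 held at least 1. These planned tests therefore leave open whether the EHMT1 siRNA is the source of the words and whether SOX8 fell through them. As many words as in the longest EHMT1 transcript were in 1.8% of such transcripts. As many as in the SOX8 3′ UTR were in 0 of 500 such UTRs (which allows up to 0.60%). This comparison was made only after the planned tests had left the question open. The words had been picked on fallen genes that include SOX8 and EHMT1, so the shares cannot be read as chances. Of the 4 words in the SOX8 UTR, GAGTCTA passed narrowly, with 4.89 against 4.85. The siRNA sequence is not given in the sources used here, and loss of EHMT1 itself stays an untested explanation for SOX8 and for the other falls.

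The fall of cell cycle genes held without scrambled replicate 2 (31 of 41 fell) and with GC content and length corrected (32 fell), which argues against either as the whole cause. Seed matches stay open: 20.7% of the fallen cell cycle genes with a searched UTR had an enriched word (6 of 29), against 13.2% in UTRs of similar content (3.8 genes), too small a difference to decide with so few genes, and the words had been picked on fallen genes that include these. Loss of EHMT1 or slower growth after the siRNA may lie behind the fall, and neither was tested.

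At least 2-fold changes were more often rises, 129 against 33, and the ratio was 3.92 without scrambled replicate 2, which argues against that library as the cause. Background reads from both strands could also raise genes at low levels. The planned test of this, the pooled share of the gained reads in strand column 4, gave 61.0% at the lowest, between the bounds set beforehand (60% or less, or over 75%), and decided nothing. In the scrambled libraries the 129 genes had a mean of 19.8% of their strand counts in column 4, against 87.1% to 89.0% over all genes. The pooled sum thus leans on genes read mostly on the other strand. A test added after the 61.0% was seen, the median share gene by gene, was 91.5% at the lowest. A loss in either column counted as no gain, so a gene that gained in strand column 4 alone took the highest share. With that limit, the value argues against background reads for most of the 129 genes but not for those that dominate the pooled sum. Loss of a repressive methyltransferase is a candidate explanation that was not tested.

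The comparison of the 3 scrambled with the 3 EHMT1 siRNA libraries gave 2304 changed genes, and the highest of the other splits of the 6 libraries into 3 and 3 gave 0 by edgeR and 0 by DESeq2 (at an unadjusted p under 0.05, 4774 genes in the real split and at most 869 in the others). Only 1 split, the real one, gave as many, but 10 splits are too few for a share under 0.05.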
